A study of Homo sapiens with 12 samples.

How the data were processed

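Immunoprecipitates and inputs of RBE cells with a control hairpin or a hairpin against NAT10 were sequenced in 3 replicates each, 12 libraries in all. Per the submitters' processing notes, fastp 0.20.1, Bowtie2 2.4.1 and the genome build hg38 were used. The peak caller, its threshold, the use of the input libraries and the pooling of replicates are not given in the sources used here. The authors deposited 1 peak list per arm in a 12-column interval format, and each peak carries a deposited score whose scale is not given in the sources used here. Most scores lie above a sharp lower edge at 10. A score of 0 was listed for 907 control and 592 knockdown peaks, and an infinite one for 67 and 60. Scores were used only to rank, filter and describe peaks within a list. The control list was matched to its arm by its name, which fits only the control titles, and the remaining list was taken as the knockdown list.

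Each peak is written as 1 block, so a span can include introns and its width is not a length of RNA. Median widths were 175 bp in the control list and 168 bp in the knockdown list. Total read depth is unknown, so no depth-based interval is given. Intervals on shares are 95% Wilson intervals, which cover counting error only and treat peaks and genes as independent, which they are not.

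Overlaps were computed with bedtools 2.31.1, with at least 1 bp on the same strand. Statistics used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. Peaks were assigned to the genes of the RefSeq annotation of the human reference assembly whose span they overlapped by at least 1 bp, on either strand. The planned assignment used exons. The annotation used here gives gene spans without exons, strand or sequence, so gene span overlap, listed beforehand as a second choice, was used instead, and gene span replaced exonic length in the matching. Of the control peaks 78.3% overlapped exactly 1 gene, and of the knockdown peaks 78.9%. Whether strand was used upstream is not given in the sources used here, so overlapping and antisense genes are uncertain, as are genes with near-identical copies.

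The gene lists, the rule for named genes and most of the other settings tried were chosen before the data were examined. The rule names NAT10 and CHAF1A, the 10 protein-coding genes with the highest peak score in the control list only, the 10 in the knockdown list only, the 5 highest in both, and up to 4 members of each of 19 gene lists, leaving out peaks that overlap more than 1 gene. Some genes that the rule names are not reported here. For each list, the share of genes with a control peak that have no knockdown peak was placed among 10000 random lists of protein-coding genes, matched on decile of the highest control score and quintile of gene span. Lists with fewer than 5 such genes got counts only. The percentile describes these peak lists and is no test of the knockdown. The 6 marker lists of neurons, astrocytes, oligodendrocytes, microglia, skeletal muscle and testis germ cells were written after neuronal genes were seen among the largest losses and before the glial values were looked at. Random placement used 100 draws of narrow peaks, up to 1000 bp, within the span of the same gene.

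The overlap and list procedures were tested on simulated data. All 11780 copies of control peaks shifted by 10 bp on the same strand were found (100%). For the lists, loss was simulated over the 9449 protein-coding genes with a control peak, in lists drawn with 30 genes. Lists without an effect were drawn from genes below the median control score. Genes with raised loss were then removed from them, so these lists could hold fewer than 30. In the first simulation, 92.5% of 40 lists with loss raised by 35 percentage points lay above the central 95% of random lists, and 9.5% of 200 lists without an effect lay outside it, 8.5% on the low side. After that result was seen, the simulation was repeated with other seeds and with 0, 20 and 40 raised lists in the pool. The share of 1000 lists without an effect outside the central 95% was then 4.9%, 6.0% and 8.1%, and the share on the low side 2.6%, 4.8% and 7.3%. Raised lists were found in 98.0% and 95.5% of cases. With matching, low percentiles are therefore called too often where other genes lose peaks strongly, and high ones too seldom, with 0.8% of lists without an effect above the central range at 40 raised lists. Without matching the error ran the other way, as the lists without an effect had low scores. In the first simulation 7.5% of them lay above the central range and 0.5% below, with 95.0% of raised lists found, and in the repeats 21.6%, 14.6% and 8.5% lay above it with 0, 20 and 40 raised lists. The matched procedure was not altered after these simulations.

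Alternatives covered the minimum overlap, the score threshold, lists of equal length, merging of peaks, gene assignment and matching. Position in untranslated and coding sequence, cytidine content and CXX repeats, and repeat-masked sequence were planned and not analysed here, because they need exons or sequence.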

Results

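The study measured N4-acetylcytidine (ac4C), an acetylated form of cytidine in RNA, in RBE cells, a human intrahepatic cholangiocarcinoma line. Cells carrying a short hairpin RNA against NAT10, the RNA cytidine acetyltransferase, were set against cells carrying a control hairpin. Fragmented RNA was immunoprecipitated with an ac4C antibody and sequenced beside its input. The 12 libraries form 4 groups of 3, an immunoprecipitate and an input in each arm. The values analysed here are 1 list of peaks per arm, the control list with 34365 peaks and the knockdown list with 28047. No list separates the replicates, so nothing here measures the spread between them and no p-value is given between arms. The sequencing depth behind the lists is unknown, and a peak can be absent because the site was not acetylated, because the RNA was scarce or because too few reads were present.

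The first question was what happened to peaks on CHAF1A, the large subunit of the CAF-1 histone chaperone that the study design singles out, and on NAT10 itself. On the plus strand of CHAF1A (chromosome 19, 4402640 to 4450830, hg38) the control list had 10 peaks and the knockdown list 4. Each of the 4 knockdown peaks overlapped a control peak, and 6 control peaks had no counterpart. The missing peaks included the one with the highest score in the control list for this gene, a 176 bp peak from 4429536 to 4429711 with a score of 18.04. NAT10 (chromosome 11, 34105629 to 34146908) had 5 peaks in both lists, and 3 of the control peaks overlapped a knockdown peak. THUMPD1, the adaptor that NAT10 uses on transfer RNA, had 1 control peak, shared with an overlapping gene and with a score of 10.64, and 0 in the knockdown list. NAT10 RNA or protein was not measured in these lists, so its peaks do not check the arm labels.

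**Figure D1:**
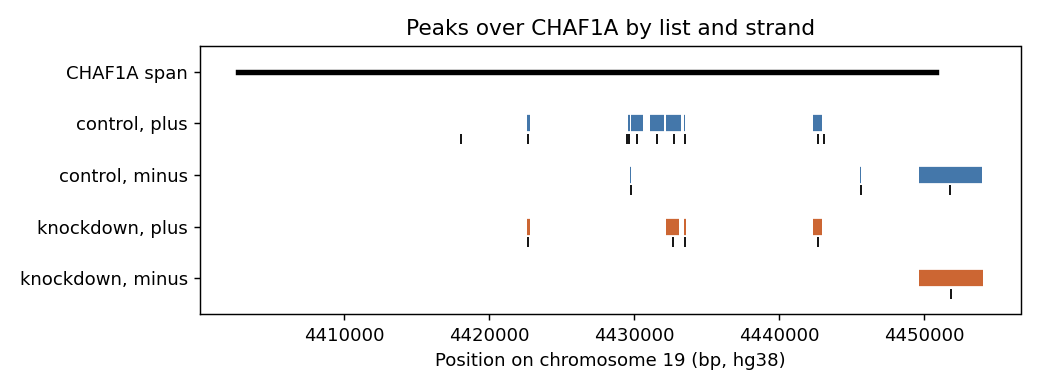
Peaks over CHAF1A in the control and knockdown lists, by strand, along chromosome 19 (bp, hg38), with bars to scale and a tick under the middle of each peak. The plus-strand row holds 10 control peaks and 4 knockdown peaks, and a wide minus-strand peak at the right end is present in both lists.

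The change on CHAF1A was not unusual for a gene with its number of peaks. Counting peaks that overlap no other gene, CHAF1A had 11 control peaks and 4 knockdown peaks. Among 220 other protein-coding genes with 10 to 12 control peaks, the median number in the knockdown list was 7 (interquartile range 2 to 10). Of these genes, 68 had fewer knockdown peaks than CHAF1A, 9 had as many and 143 had more. They were chosen on control peak number only, not on score, gene span or expression, and genes of the nervous system were not left out.

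Across the transcriptome, the protein-coding genes with a peak in the control list only included DMXL2, PRKCE, ZNF891, GTF2IRD2, MUC7 and EXOC5, and those with a peak in the knockdown list only included PPA2, ARMC10, TMEM106C, TMPO, SF3A3 and EXOSC8. DMXL2, a regulator of the vesicular proton pump, had 17 control peaks with a highest score of 257.6 and 0 knockdown peaks. PRKCE, a protein kinase C, had 10 control peaks and 0 knockdown peaks. TMPO, a nuclear envelope protein, had 0 control peaks and 5 knockdown peaks with a highest score of 52.49. SF3A3, a splicing factor subunit, and POLE3, a DNA polymerase epsilon subunit, each had 0 control peaks and 2 knockdown peaks. The remaining control-only genes with the highest scores were PLEKHG7, SERPINA6, SORCS2 and MRPL13, and the remaining knockdown-only ones were RTKN2, GUF1 and PWWP3A. Some of the highest-scoring control peaks were wide spans, 106723 bp on SORCS2, 41295 bp on MUC7 and 12860 bp on PLEKHG7. Others were narrow, such as PRKCE (100 bp) and EXOC5 (419 bp). The top MRPL13 peak, 14287 bp wide, ends at 120395447 and reaches only the edge of the gene, which starts at 120395437. Among the knockdown-only genes named, the widest such peak was 6430 bp, on RTKN2.

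Peaks of the highest scores recurred on EIF4G2, a translation initiation factor, with 10 peaks in both lists, on VIM, which encodes vimentin, with 10 in both, and on EPS8L2, an actin regulator, with 12 control and 8 knockdown peaks. ATP2B1, a plasma membrane calcium pump, had 16 control and 6 knockdown peaks, and CAMK2A, a calcium-dependent kinase abundant in neurons, had 9 control peaks and 1 knockdown peak. The highest-scoring control peaks of DMXL2, EIF4G2, EPS8L2, ATP2B1 and CAMK2A lay on the strand opposite to most of their other peaks, and VIM had such peaks on both strands, so their assignment to these genes is uncertain. In total 16364 genes had a control peak and 13816 a knockdown peak, with 11052 in both. With the control list shortened to the length of the knockdown list by score, the order turned, with 13382 genes against 13816. Then 3956 were in the control list only and 4390 in the knockdown list only. That cut drops the 1535 control peaks with a score under 10, mostly wide, and keeps the 1244 such knockdown peaks. In the upper 50% of each list by score the order held, with 10719 genes against 8765. Of these, 4403 were in the control list only and 2449 in the knockdown list only. Among protein-coding genes, 6963 had peaks in both lists, 2486 in the control list only (26.3% of 9449, 95% interval 25.4 to 27.2) and 1466 in the knockdown list only (17.4% of 8429). At a score of 20 or more, a setting added after seeing the data, 1296 protein-coding genes were in the control list only and 1324 in the knockdown list only. Of the 3056 long noncoding RNA genes with a control peak, 47.2% had none in the knockdown list, but counting only peaks that overlap no other gene the number was 545, of which 63.5% had none.

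Chromatin remodelling, ribosomal protein, translation factor, replication and cell cycle, and biliary genes had a knockdown peak more often than matched genes. So did histone enzyme and splicing genes under the main matching. Expression is not in the peak lists and was not matched. All 39 chromatin remodelling genes with a control peak had a knockdown peak, against 23.6% without one in random lists matched on control score and gene span. MTA1, a subunit of the NuRD complex, had 14 control and 13 knockdown peaks. Of 59 cytosolic ribosomal protein genes with a control peak, 2 had no knockdown peak (3.39%, random 21.1%), RPL14 and RPL37. RPLP1 had 4 control and 3 knockdown peaks. Of 35 translation factors 1 had none (2.86%, random 20.5%), of 34 replication and cell cycle genes 2 had none, CCNE1 and CCNB1 (5.88%, random 23.9%), and of 37 splicing genes 2 had none, SRSF4 and SRSF7 (5.41%, random 18.1%). All 32 biliary and cholangiocarcinoma genes with a control peak had a knockdown peak, among them NOTCH2 with 6 and 11 peaks and EGFR with 15 and 17. JARID2 was the 1 of 28 histone methyltransferase and acetyltransferase genes without a knockdown peak (3.57%, random 20.8%), and KMT2A had 20 control and 6 knockdown peaks.

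These lists lay at or below percentile 1.27 of 10000 random lists, but matched on the number of control peaks the histone enzyme and splicing lists came inside the central 95% (percentiles 6.00 and 6.13). In simulated data, up to 8.5% of lists without any effect fell below percentile 2.5 when other genes in the pool had a raised loss. How often lists without an effect reach 1.27 or less was not counted. The percentiles therefore describe these lists and carry no error rate. The share of genes with more knockdown than control peaks was compared as well, a comparison chosen after seeing the data. More knockdown than control peaks were found on 21 of 39 translation factors with any peak, against 34.5% in random lists matched on total peak number (percentile 99.4), on 21 of 35 ribosome biogenesis genes (percentile 99.9) and on 19 of 37 replication and cell cycle genes (percentile 98.7). Ribosomal protein genes (percentile 97.1), splicing (93.1), chromatin remodelling (84.6), histone enzyme (63.3) and biliary genes (33.7) lay inside the central 95%. MCM4, a subunit of the replicative helicase, had 4 control and 5 knockdown peaks.

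KRAB zinc finger genes, whose products repress transposable elements, had a control peak without a knockdown peak more often than matched genes. The share with a knockdown peak only lay at the upper edge of its random range. Of 36 with a control peak, 21 had no knockdown peak (58.3%, 95% interval 42.2 to 72.9), against 23.9% in matched random lists (percentile 100). ZNF675 had 1 control peak with a score of 36.3 and ZNF184 had 2, and neither had a knockdown peak. ZNF841 had 1 peak in both lists and ZNF124 had 2 in both. Of the 23 with a knockdown peak, 8 had no control peak (34.8%, 95% interval 18.8 to 55.1). In random lists matched on knockdown score and gene span the share was 17.1% (percentile 98.4), a comparison added after seeing the data. The KRAB share equals the upper limit of the central 95% of those lists, and matching on peak number was not run for it. More knockdown than control peaks were found on 27.3% of the KRAB genes with any peak, inside the central 95% of random lists (percentile 21.8). The knockdown-only genes included ZNF91, a repressor of SVA elements, with 0 control and 4 knockdown peaks. Reads of zinc finger paralogs can be split between copies, and each of these counts is uncertain for that reason.

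Genes of the transposable element silencing list, which shares ZNF91 and ZNF93 with the KRAB list, mostly had peaks in both arms. Of 24 with a control peak, 22 had a knockdown peak (8.33% without, random 26.1%, percentile 1.42, or 3.98 when matched on the number of control peaks). TRIM28, the corepressor that KRAB proteins recruit, had 11 control and 12 knockdown peaks, and EHMT1, a histone H3 methyltransferase, had 14 and 11. TASOR, a subunit of the HUSH complex, had 4 control peaks and 0 knockdown peaks. DNMT3B had 1 and 0, with a score of 10.17, near the lower edge of 10. Of the 21 CAF-1 and histone chaperone genes with a control peak, 18 had a knockdown peak, and CHAF1B and DAXX were among the 3 that did not (14.3%, random 27.1%, percentile 8.61). Each of these 2 genes had 1 control peak near the lower edge of 10, with scores of 10.07 and 11.09. Of 13 double-stranded RNA sensing and interferon genes with a control peak, 5 had none in the knockdown list, including STAT2 and DDX60 (38.5%, random 24.2%, percentile 88.7). MAVS had 1 control and 2 knockdown peaks.

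The remaining fixed lists lay inside the central 95% of random lists or were too small for a percentile, but matched on the number of control peaks ribosome biogenesis (percentile 1.90), DNA damage response and apoptosis (2.31) and histone genes (1.21) lay below it. Of 28 ribosome biogenesis genes 3 had no knockdown peak (10.7%, percentile 3.27), and TCOF1 had 14 control and 12 knockdown peaks. Of 16 DNA damage response and apoptosis genes 1 had none, BID (6.25%, percentile 4.24), and BAX had 5 control and 4 knockdown peaks. All 9 replication-dependent histone genes with a control peak had a knockdown peak (percentile 8.83). Of 6 hepatocyte markers 4 had no knockdown peak, including ALB (66.7%, percentile 92.3), and of 9 fibroblast and stromal markers 4 had none, including SPARC (44.4%, percentile 91.8). The fibroblast and stromal list also had 2 genes with a knockdown peak only, and 44 control and 48 knockdown peaks in all. Immune markers had peaks on 3 genes in both lists, among them CD68 with 5 peaks in both. Neither list had a peak on the mitochondrial genome.

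**Figure D2:**
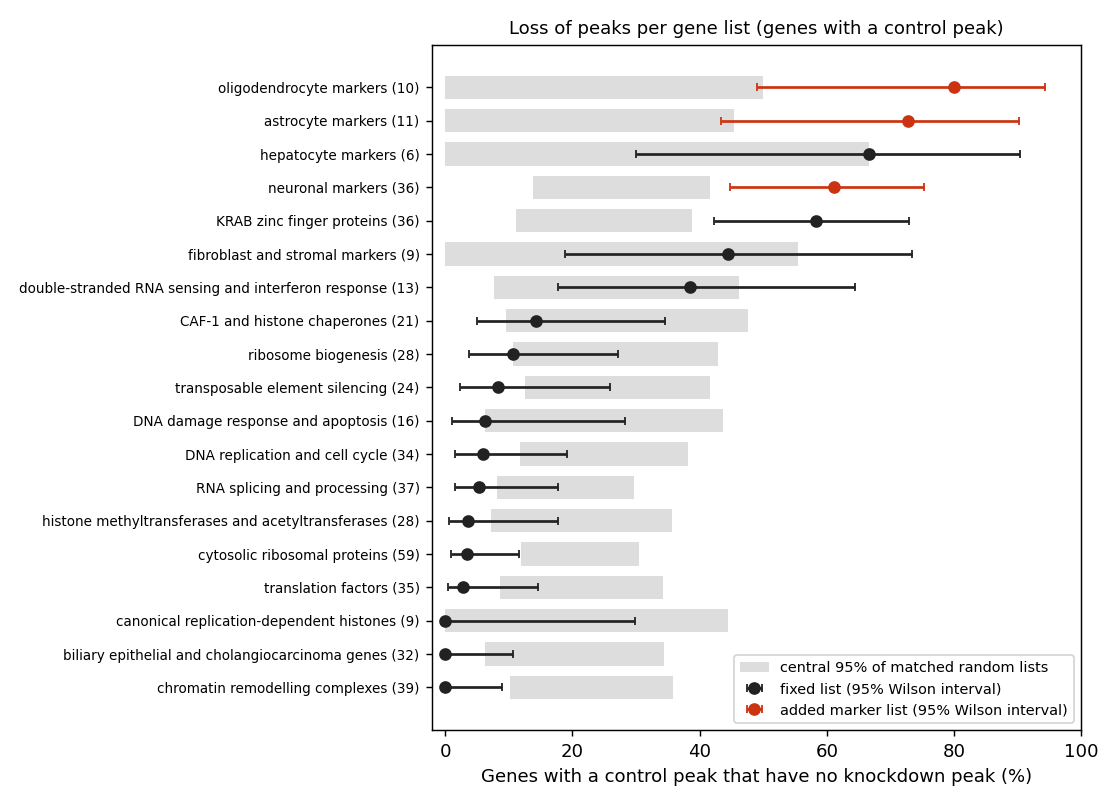
Share (%) of the genes with a control peak that have no knockdown peak, per gene list (number of such genes in brackets), as points with 95% Wilson intervals over the central 95% of 10000 matched random lists. KRAB zinc finger genes (58.3%) and the neuronal, astrocyte and oligodendrocyte markers added after seeing the data lie above their random ranges.

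The genes with the largest drop in peak number included several large genes known from the nervous system. PCLO, a scaffold of the presynaptic active zone, had 28 control peaks and 1 knockdown peak, ANK2 and ANK3, which anchor membrane channels, had 25 and 26 control peaks and 0 knockdown peaks, and SCN2A, a neuronal sodium channel, had 26 and 1. MAP2, a dendritic microtubule protein, had 20 and 0. Counting only peaks that overlap no other gene, 96 protein-coding genes had at least 10 fewer peaks in the knockdown list and 5 had at least 10 more. Those 5 were UBR4 with 12 control and 33 knockdown peaks, PTPRS with 16 and 28, GALNT2 with 6 and 17, NUP98 with 2 and 12, and NBPF19 with 12 and 44, a member of a family of near-identical copies. These genes were chosen after their values were seen.

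Lists of cell type markers were therefore added after seeing the data. Of 36 neuronal markers with a control peak, 22 had no knockdown peak (61.1%, random 28.2%, percentile 100), and their peaks numbered 164 in the control list and 46 in the knockdown list. The GABA receptor gene GABRB2 had 12 control peaks and 0 knockdown peaks, and SNAP25, a synaptic fusion protein, had 13 and 4. Of 11 astrocyte markers 8 had no knockdown peak (72.7%, percentile 99.99), among them the glutamate transporter SLC1A2 with 10 control peaks. Of 10 oligodendrocyte markers 8 had none (80%, percentile 99.99), among them the myelin gene MBP with 5 control peaks. TUBB3 had 5 control and 8 knockdown peaks and CLU 4 and 6, and GFAP, MOG and MOBP had no peak in either list. Peaks on markers of microglia (1 control gene, 0 knockdown), skeletal muscle (4 and 3) and testis germ cells (4 and 3) were few. Without the genes of these marker lists, 5270 genes in place of 5312 had a control peak only.

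The knockdown list held 81.6% as many peaks as the control list. By score, peaks under 20 numbered 30122 and 23855 (79.2%), peaks with a score of 20 or more 4243 and 4192 (98.8%), and peaks with a score of 50 or more 660 and 749 (113%). By width, peaks up to 1000 bp numbered 23695 and 19241 (81.2%), those over 1000 bp 10670 and 8806 (82.5%), and among the latter those over 10000 bp 4861 and 2793 (57.5%). Scores are the authors' own and the lists may differ in depth, so these ratios describe the lists as they stand. Of the control peaks 45.5% (95% interval 44.9 to 46.0) overlapped a knockdown peak on the same strand, and of the knockdown peaks 55.6% (55.0 to 56.2) overlapped a control peak. From a score of 10 upwards, sharing went from 29.4% of control peaks with a score of 10 to 11 up to 81.8% (78.7 to 84.6) at 50 or more. Peaks with a score under 10 did not follow this order, with 58.1% of 1535 control peaks and 72.7% of 1244 knockdown peaks shared. They were wide, with median widths of 27695 and 16715 bp. Of those up to 1000 bp, 46.25% of 240 control and 44.3% of 228 knockdown peaks were shared. Narrow knockdown peaks inside 1 gene were shared in 50.3% of cases, against 17.4% (range 16.7 to 18.1) when they were placed at random within the span of the same gene, introns included.

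**Figure D3:**
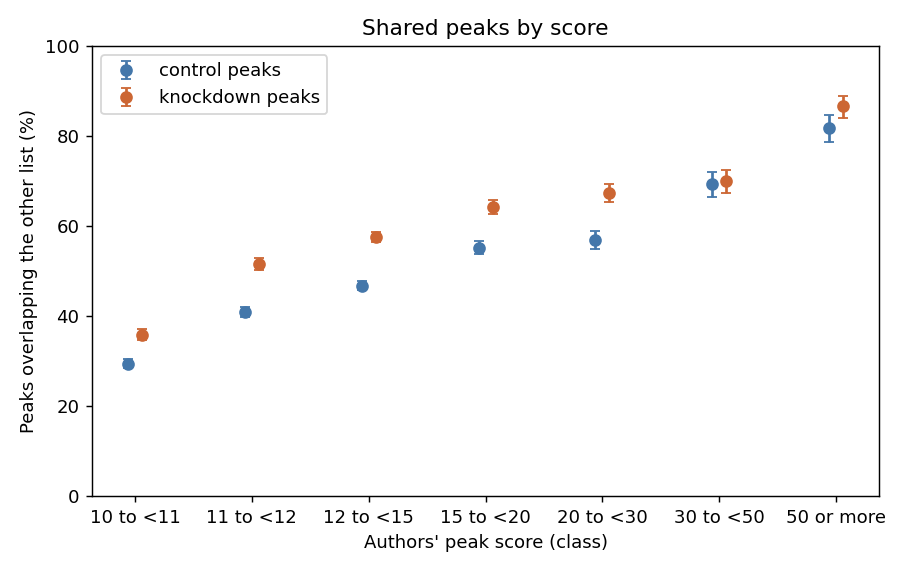
Share (%) of control peaks and of knockdown peaks that overlap a peak of the other list, by class of the authors' peak score within each list, for scores of 10 or more, with 95% Wilson intervals. Over these classes the share goes from 29.4% to 81.8% for control peaks and from 35.8% to 86.6% for knockdown peaks.

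Peaks of the control list lay more often near the end of protein-coding genes. Of 18347 narrow control peaks, 30.6% (29.9 to 31.3) fell in the last 10% of the gene span, against 22.6% (21.9 to 23.2) of 14619 knockdown peaks. The first 10% held 7.23% and 9.10%. Direction was taken from the strand of the peak, and exons, coding sequence and untranslated regions were not analysed here.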

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

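Settings on peak width, scores of 20 or 50 and more, peaks in 1 gene, genes with peaks in both lists and the marker lists were chosen after seeing the data. No paired analysis was possible because the lists carry no replicate numbers, although the library labels share them, and for the same reason no replicate was left out. Settings that need exons or sequence were not run. The shares of shared control and knockdown peaks, 45.5% and 55.6%, moved to 40.8% and 48.5% with 50% of the peak covered, 32.6% and 39.97% with reciprocal overlap, 50.1% and 61.3% within 100 bp, 36.7% and 45.1% in the upper 50% of each list by score, 48.1% and 49.2% in lists of equal length, 37.1% and 45.9% for peaks up to 1000 bp, and 34.5% and 34.9% at a score of 20 or more. Stricter overlap lowers a share by construction. Settings by score or width cut both lists, so counterparts outside the cut no longer count, which also lowers the share of the peaks kept. Against the full knockdown list, 56.9% of control peaks with a score of 20 to 30, 69.3% at 30 to 50 and 81.8% at 50 or more were shared. For knockdown peaks against the full control list these shares were 67.4%, 70.0% and 86.6%. The cause of the remaining shifts was not tested. Knockdown peaks as a share of control peaks were 57.5% over 10000 bp, 98.8% at a score of 20 or more and 113% at 50 or more, where the direction reversed, and the cause was not tested. Genes with a control peak, a knockdown peak, a control peak only and a knockdown peak only numbered 9449, 8429, 2486 and 1466 among protein-coding genes, 9162, 7925, 2969 and 1732 for peaks in 1 gene, and 2745, 2773, 1296 and 1324 for protein-coding genes at a score of 20 or more, where the knockdown-only genes outnumber the control-only ones. The upper 50% of each list left 10719 and 8765 genes with a peak, and lists of equal length, where only the control list is shortened, turned the order of the arms, with 13382 control against 13816 knockdown genes and 3956 control-only against 4390 knockdown-only genes. Of 75 list percentiles recomputed for loss of peaks, 66 kept their side of the central 95%, including those of KRAB and neuronal, astrocyte and oligodendrocyte genes under every setting run. Matched on the number of control peaks, transposable element silencing (percentile 3.98), histone methyltransferases and acetyltransferases (6.00) and splicing (6.13) came inside, and ribosome biogenesis (1.90), DNA damage response and apoptosis (2.31) and histones (1.21) went outside. With peaks in 1 gene, transposable element silencing was at 4.26 and histone chaperones at 2.24, and hepatocyte markers were at 97.6 among unmatched lists, a setting that placed up to 21.6% of simulated lists without an effect above the central range. The cause was not tested. The last 10% of the gene span held 28.1% of control and 20.5% of knockdown peaks in the upper 50% by score, and 28.2% and 23.1% in genes with peaks in both lists, so the order of the lists held. CHAF1A had fewer knockdown peaks under each setting run, 2 against 6, 4 against 8 and 4 against 9. Unknown depth limits every comparison of peak number.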

Other observations

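The tests of explanations below were framed after the patterns were seen, although matching the fixed lists on the number of control peaks had been planned as a setting. Only the glial values were unseen when their test was written.

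The genes named here were chosen after their values were seen, and every peak that overlaps them was counted, of any width, unless stated otherwise. By class of small noncoding RNA gene, only narrow peaks that overlap no other gene were counted, which leaves out small RNAs inside host genes. Such peaks covered 16 copies of 5S ribosomal RNA in both lists, 26 and 25 small nuclear RNA genes and 6 and 7 small nucleolar RNA genes, with near-identical copies that share reads. Of 429 transfer RNA genes, 0 had such a peak in either list. SNORD13, the guide RNA for acetylation of 18S ribosomal RNA, had 1 peak in both lists. RN7SK had 1 peak in both and RPPH1, the RNA of ribonuclease P, had 2 in both. MALAT1 had 26 control and 29 knockdown peaks and NEAT1 had 4 and 9. TERC, the telomerase RNA, had 1 control peak with a score of 10.19 and 0 knockdown peaks. FN1, which encodes fibronectin, had 0 control peaks and 8 knockdown peaks that overlap no other gene. Peaks in 1 protein-coding gene in the knockdown list ranged from 60.8% of the control number on chromosome X and 64.6% on chromosome 4 to 103% on chromosome 20.

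Markers of neurons, astrocytes and oligodendrocytes had peaks in the control list that were mostly absent from the knockdown list, and how many of these genes RBE cells express was not tested. Gene length and scores near the threshold are argued against as the whole cause, since the neuronal list lay at percentile 100 among random lists matched on gene span and again at 100 when matched on score and span. RNA of brain tissue in control libraries is a candidate explanation, as 62.5% of the 16 oligodendrocyte markers had a control peak, MBP among them, although with peaks in 1 gene only 5 of the 16 remain (4 of them without a knockdown peak) and GFAP, MOG and MOBP had no peak. Among random lists of the same span, that share lay at percentile 93.0, inside the central 95%. The shares of astrocyte (68.8%) and neuronal markers (92.3%) lay at percentiles 97.6 and 100. Markers of microglia, another brain cell type, went the other way, with a control peak on 1 of 10 (random 38.8%, percentile 2.7). Neural gene expression in the control cells, a difference that depends on NAT10, and which of the 3 control libraries carries the peaks stay open, because the lists hold no input levels and no replicates.

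KRAB zinc finger genes had no knockdown peak more often than matched genes. Of those with a knockdown peak, 34.8% had no control peak (percentile 98.4), a share equal to the upper limit of its random range. Matching on peak number was not run for this share, so whether KRAB genes also gained peaks more often than matched genes stays open. For the loss, scores near the threshold are argued against, since among genes with a control score of 15 or more 11 of 19 KRAB genes had no knockdown peak (percentile 100), and so is a small number of peaks per gene (percentile 99.94 when matched on it). Lower KRAB expression, loss of acetylation, reads split between paralogs and the source of the neural peaks stay open and were not tested.

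Of the 34365 control peaks, 18743 had no counterpart in the knockdown list. Calls near the threshold may account for part of this, as sharing was lowest at scores of 10 to 11. Control peaks with a score under 10 were shared more often (58.1%), but their median width was 27695 bp. The 240 of them up to 1000 bp were shared in 46.25% of cases, against 29.7% of such narrow peaks at scores of 10 to 11. At a score of 50 or more, 81.82% of control peaks were shared, with an upper bound of 84.6%, and 79.37% of the 252 knockdown peaks up to 1000 bp, with an upper bound of 83.9%, which argues against the threshold as the whole cause. For the 163 control peaks up to 1000 bp the share was 88.34% with an upper bound of 92.4%, above the 90% set as the limit, so for these it stays open. The spread between replicate lists, which would show how much turnover occurs without a knockdown, was not analysed here.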
